A study of Drosophila melanogaster with 16 samples.

How the data were processed

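RNA was isolated with Trizol from glia sorted for tdTomato and STAT-reporter GFP, per the labels, and poly(A) RNA was made into cDNA with the Smart-Seq V4 kit and into libraries with Nextera XT. These kits keep no strand information and no molecular identifiers, so antisense overlaps cannot be told apart and PCR copies count as reads. The submitters' processing notes name the aligner GSNAP and the genome BDGP6. The deposited values are whole-number read counts per gene under FlyBase identifiers, with 1 column per sample and no normalisation, as made by the authors. The counter, its settings and the annotation release are not given in the sources used here. Paralogs that share reads, such as the Hsp70, cecropin, attacin and glutathione transferase copies, are uncertain for this reason.

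The 16 columns were grouped by the labels into mock or Ecc15 and GFP-positive or GFP-negative, 4 libraries each, and no library was left out of the comparisons as first run. No pair of libraries held identical counts. Gene symbols and coordinates came from the Ensembl 115 annotation of BDGP6.54. Of 17559 identifiers, 17253 had a symbol there, and the 306 others, mostly retired, took 2.31 to 3.5% of the counts of a library and stayed in the tests under their identifier. Of 486 members of the gene lists, 468 were matched by symbol. The other 18 were not used here, among them Drs, InR, para, VAChT, wupA and FASN1.

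Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the group as factor, which kept 11752 genes, and libraries were scaled by TMM factors. Quasi-likelihood models with 1 coefficient per group were fitted to all 16 libraries (glmQLFit, common biological coefficient of variation 0.584, prior degrees of freedom 3.51) and 7 contrasts were tested with the two-sided glmQLFTest. The contrasts were positive against negative in mock and in infected flies, infected against mock in either fraction, their difference, and the averages over the other factor. P-values were adjusted by Benjamini-Hochberg within a contrast and called under 0.05. Standard errors are the size of the log2 fold change over the square root of F. CPM in the text are TMM-scaled with mean and SD over the 4 libraries of a group, and library scores and principal components used log2 CPM with a prior count of 2.

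The 31 gene lists, written before the data were examined like the groups, contrasts, thresholds and most other settings, cover JAK/STAT and Turandot genes, antimicrobial peptides, IMD and Toll, JNK, heat shock and oxidative stress genes. They also cover glycolysis, sugar transport, the TCA cycle, the nuclear and mitochondrial respiratory chain genes, fatty acid oxidation, lipid synthesis, glutamate handling, engulfment, starvation, the clock and transmitter receptors. The last are marker lists of pan-glial, ensheathing, astrocyte-like, cortex and surface glia, neurons, photoreceptors, hemocytes, fat body, muscle and sex composition, with ribosomal proteins. Lists with at least 3 tested members were tested by camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast. They were tested again with an estimated correlation, with fry and with the replicate number as a block. Members called were counted after adjustment over all genes and adjusted over the list alone. With an estimated correlation the calls that held were surface glia in both infection states and antimicrobial peptides in GFP-positive glia after infection.

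Genes named were the 10 higher and 10 lower with the smallest p among called genes of at least 5 mean CPM, passing over names beginning with CG or CR, with repo, Stat92E, dome and Socs36E and up to 4 members of each list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

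The settings varied were a stricter filter (5 CPM in 4 libraries), no filter, RLE factors, library sizes alone, the replicate number as a block, a block within infection state, each library left out in turn, only the groups compared, robust estimation, DESeq2 1.42.0 and limma with voom and library quality weights. Leaving out the negative libraries numbered 1 or those numbered 3, and repeating the list tests without each library, were added after seeing the data. Whether equal replicate numbers mark pairs was checked by correlating residuals of libraries of the same number. Only the GFP-negative libraries of mock and infected flies correlated above 0.1 at all 4 numbers (0.53, 0.12, 0.12 and 0.15), so the numbers were given as a block only as an alternative. That block was shared by both fractions, or by the fractions within an infection state. No fit gave the negative libraries of mock and infected flies a block of their own. Nothing in the labels says that the 4 libraries of a group came from separate flies, pools or sorts. The p-values therefore measure only the spread between these samples, which may be technical.

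The tests were tested on simulated data, negative binomial counts with the means, dispersions and library sizes of these libraries, in which 200 genes were changed. Of genes changed 2-fold, 14.2% were recovered between infected and mock GFP-positive glia and 11.2% in GFP-negative glia, and of genes changed 4-fold 62.6% and 59.9%. False calls numbered 0 to 6 per run. The groupings were tested against every other split of the libraries of a pair of groups into 4 and 4, of which there are 35 with the real one. For contrasts of all 16 libraries, 100 splits were used, the real one and random ones that exchanged libraries within a fraction or infection state. For the difference and the average of the infection responses, 100 further splits, added after seeing the data, parted every pair of negative libraries of equal number.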

Results

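The transcriptomes of glia sorted from the brains of young Drosophila melanogaster were measured in 16 RNA-seq libraries. All glia carried tdTomato, driven by the glial driver repo-Gal4, and were sorted by a GFP reporter of STAT activity into a GFP-positive and a GFP-negative fraction. STAT is the transcription factor of the JAK/STAT pathway, which answers to cytokines of the Unpaired (upd) family. Flies were either mock-treated or infected for 4 h with Ecc15, a strain of the gut-pathogenic bacterium Erwinia carotovora. The labels also carry the mark "3d", whose meaning they do not state. The 4 combinations of fraction and infection state held 4 libraries each, numbered 1 to 4. According to its title, the series asks how inflammatory cytokines released by the gut act on ensheathing glia, their metabolism and the sense of smell.

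Total counts per library were high and similar between groups. The 4 mock GFP-positive libraries held 55507787 to 72253895 counts each, the 4 mock GFP-negative libraries 48371904 to 71468500, the 4 Ecc15 GFP-positive libraries 59613335 to 69609459 and the 4 Ecc15 GFP-negative libraries 60136920 to 86618487. Detected genes numbered from 10734 to 13720 per library. The mitochondrial ribosomal RNA mt:lrRNA took 10.56 ± 1.74% of the counts (mean ± SD, n = 4) in mock GFP-positive, 14.43 ± 3.08% in mock GFP-negative, 8.45 ± 2.29% in Ecc15 GFP-positive and 11.8 ± 5.35% in Ecc15 GFP-negative libraries. The first principal component carried 37% of the variance and separated the sorted fractions. The second carried 13.9%.

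**Figure D1:**
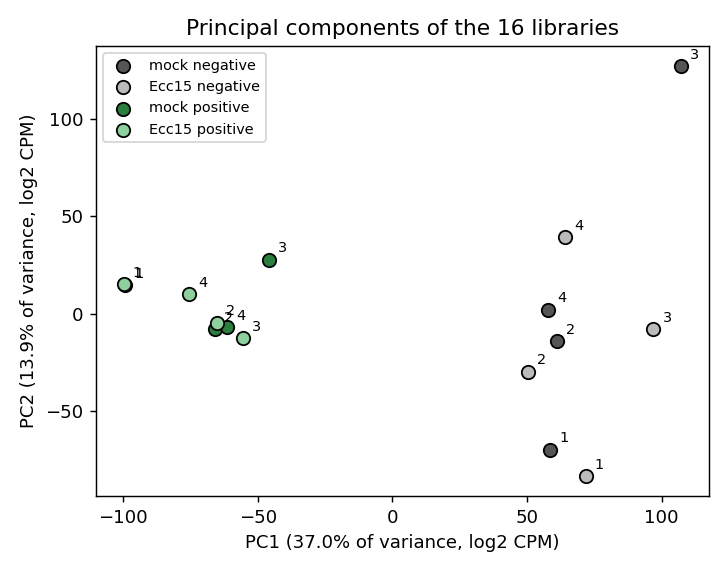
Principal components 1 (x axis, 37% of variance) and 2 (y axis, 13.9%) of log2 CPM in the 16 libraries. The replicate number is beside each point, and color marks fraction and infection state. The GFP-positive libraries lie between -99.8 and -45.8 on the first component and the GFP-negative libraries between 50.4 and 107.1.

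The first comparison asks how STAT-reporter-positive glia differ from the remaining glia in uninfected flies. Nt5a, a nucleotidase, rose in GFP-positive relative to GFP-negative glia of mock flies from 89.8 ± 10.9 to 615 ± 74.3 CPM (mean ± SD, n = 4 per group), a 6.85-fold difference. List, a solute carrier of the neurotransmitter transporter family, rose 17-fold from 62.6 ± 6.23 to 1065 ± 166 CPM. SPARC, a collagen-binding matrix protein, was 10.9-fold higher at 1800.4 ± 183 CPM. Timp, an inhibitor of matrix metalloproteinases, was 16-fold higher at 719 ± 117 CPM. In the other direction, the calcium-binding protein gene Scp2 fell from 988 ± 471 to 87.3 ± 25.6 CPM and the glutamate-gated chloride channel gene GluClalpha from 1140 ± 647 to 147 ± 38.9 CPM. In all, 1571 of 11752 tested genes were higher and 1325 lower in the GFP-positive fraction (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), of which 1076 and 929 differed at least 2-fold. Leaving out mock positive library 1 lowered the second count to 839.

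The 10 genes higher with the smallest p-values, in log2 fold change ± SE, were Nt5a (2.78 ± 0.19; FBgn0035204, chromosome 3L 1304850 to 1307418; adjusted p = 6.05e-07), List (4.09 ± 0.28; FBgn0034381, 2R 18727817 to 18730281; adjusted p = 6.05e-07), ClC-a, SPARC, sgl, Oatp58Dc, Timp, Gel, DNaseII and Pcyt2. ClC-a, a chloride channel (FBgn0051116, 3R 11797244 to 11813207), changed by 3.65 ± 0.26, and SPARC (FBgn0026562, 3R 26869238 to 26871995) by 3.45 ± 0.27. The organic anion transporter Oatp58Dc changed by 2.98 ± 0.24, the actin regulator Gel by 2.56 ± 0.21 and Pcyt2, of phosphatidylethanolamine synthesis, by 3.45 ± 0.30. The UDP-glucose dehydrogenase sgl changed by 2.34 ± 0.18 and the acid nuclease DNaseII by 3.21 ± 0.27. All 4 GFP-positive libraries lay above all 4 GFP-negative libraries for Nt5a, List, ClC-a, SPARC, Timp, Gel and Pcyt2.

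Among the 10 genes lower were the sodium-driven anion exchanger Ndae1 (-2.40 ± 0.30, adjusted p = 5.12e-05; FBgn0259111, 2L 7223328 to 7249343) and SmydA-8, which was 35.1-fold lower and close to absent from the GFP-positive libraries at 2.13 ± 0.78 CPM. The RNA-binding protein gene cpo changed by -2.50 ± 0.31, the receptor phosphatase gene Ptp36E by -1.62 ± 0.20, CRMP by -1.78 ± 0.23 and the junction protein gene cno by -1.55 ± 0.20. The transcription factor gene Ets65A changed by -2.92 ± 0.40, Scp2 by -3.50 ± 0.46, GluClalpha by -2.96 ± 0.40 and the T-type calcium channel gene Ca-alpha1T by -2.39 ± 0.33. For Ndae1, SmydA-8, cpo, Ptp36E, Scp2 and GluClalpha, all 4 GFP-positive libraries lay below all 4 GFP-negative libraries.

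Genes that bear on the sort itself moved as follows. Socs36E, the feedback inhibitor and transcriptional target of STAT, rose from 80.6 ± 4.57 to 222 ± 113 CPM (log2 1.46 ± 0.28, adjusted p = 0.00183). The receptor gene dome rose by 0.86 ± 0.29 (adjusted p = 0.0426), a call lost, at adjusted p = 0.0598 to 0.149, when any library other than mock positive 3 or mock negative 1 was left out. Stat92E itself did not pass the test (-0.07 ± 0.15, adjusted p = 0.784), at 126 ± 26.5 CPM in positive and 132 ± 11.9 CPM in negative libraries. The glial transcription factor gene repo was at 337 ± 69.6 CPM in positive and 151 ± 78.7 CPM in negative libraries and did not pass the test in mock flies (1.16 ± 0.47, adjusted p = 0.0853). The JAK/STAT list had 5 of 15 members higher and 2 lower (7 and 2 adjusted over the list alone), and the list test did not call it (median log2 0.33, camera adjusted p = 0.369). Its other higher members included the transcription factor gene zfh1 (1.25 ± 0.27) and the ligand genes upd2 and upd3, at 1.45 and 1.88 CPM in positive libraries and close to 0 in negative libraries. The repressor gene chinmo was among the lower (-1.52 ± 0.34). The 4 tested Turandot stress genes gave no call (median 0.24, camera adjusted p = 0.938), and their transcripts were close to the floor.

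Markers of glial subtypes parted in direction. The blood-brain barrier list had 9 of 12 members higher and none lower (the same counts adjusted over the list alone), with a median log2 fold change of 3.15 (camera adjusted p = 4.8e-07; adjusted p = 0.00913 with an estimated correlation). The trehalose transporter Tret1-1 rose 56.8-fold from 43.4 ± 20.9 to 2462 ± 1491 CPM, and the receptor gene moody rose by 2.53 ± 0.28. All 3 ensheathing markers rose (median 1.43, camera adjusted p = 0.000684; adjusted p = 0.17 with an estimated correlation), led by the transporter gene rumpel, at 134 ± 53 CPM in negative and 1476 ± 111 CPM in positive libraries. The glutamate transporter Eaat2 rose by 1.43 ± 0.31, and drpr, an engulfment receptor gene, by 0.65 ± 0.20. The drpr call was lost, at adjusted p = 0.0516 to 0.147, without any library other than mock positive 3 or mock negative 4. Of 3 cortex glia markers, zyd (2.82 ± 0.30) and wrapper (2.39 ± 0.43) rose and 1 fell (median 2.39, camera adjusted p = 0.0339; adjusted p = 0.304 with an estimated correlation), a list call lost without mock negative library 1 (adjusted p = 0.127) or 4 (0.051). Astrocyte-like markers went the other way, with 1 of 5 lower and 4 adjusted over the list alone (median -1.35, camera adjusted p = 0.024; adjusted p = 0.462 with an estimated correlation; 0.0614 without mock negative library 4). The member called, ebony (e), changed by -3.97 ± 0.76, while the astrocyte-like marker alrm stood at -1.39 ± 0.57 (adjusted p = 0.091, but -1.92 and 0.0337 without mock positive library 3). The pan-glial list was near 0 (median 0.03, mean -0.44, camera adjusted p = 0.697), and library-size scaling alone turned its median to -0.03. Its single call was the sodium pump subunit gene nrv2 (1.41 ± 0.30).

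**Figure D2:**
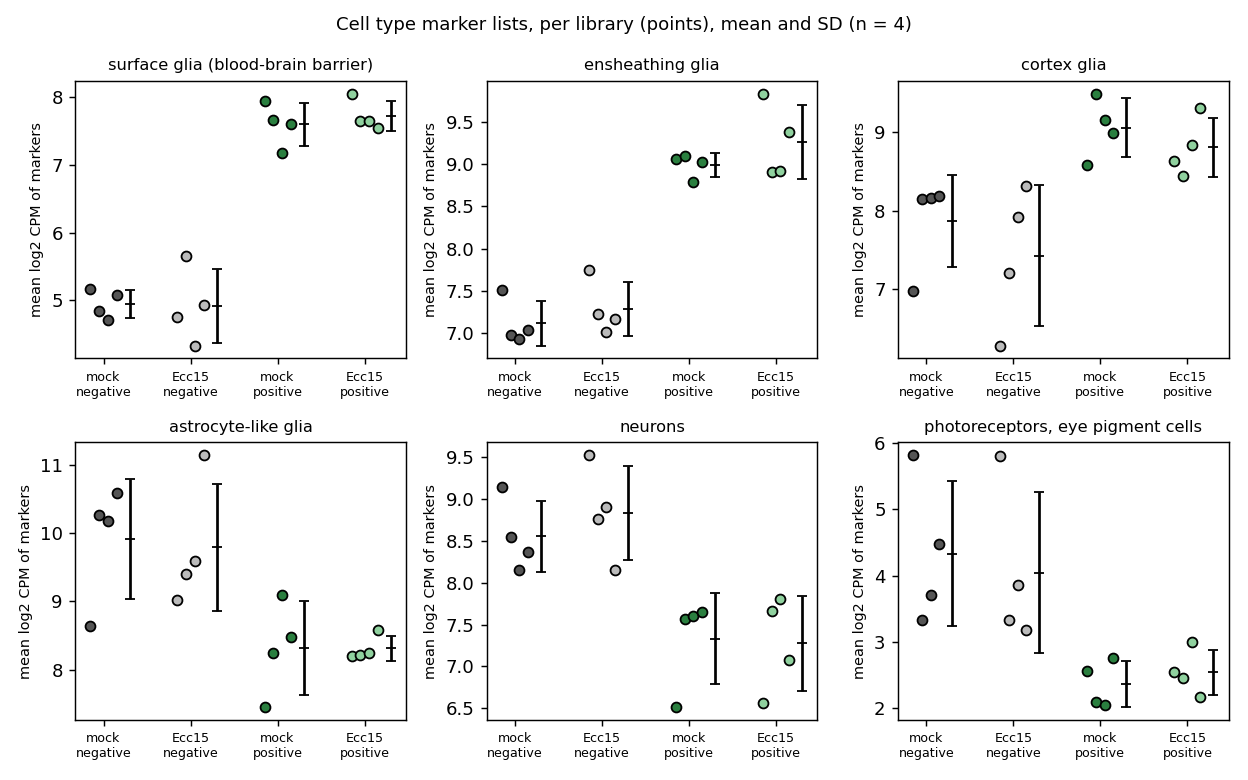
Mean log2 CPM of the markers of 6 cell types (1 panel each) in each library (points), with mean and SD (n = 4) for the 4 groups. Blood-brain barrier markers averaged 7.6 in mock positive against 4.94 in mock negative libraries, and neuronal markers 7.33 against 8.55.

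Transcripts of neurons and of the eye were higher in the GFP-negative fraction. Of 16 neuronal markers, 15 were lower in GFP-positive glia (median -1.35, camera adjusted p = 4.91e-07; adjusted p = 0.387 with an estimated correlation), and adjusted over the list alone 15 were lower and 1 higher. The neuronal RNA-binding protein gene elav changed by -0.92 ± 0.19 and the acetylcholine synthesis gene ChAT by -1.71 ± 0.36. The photoreceptor list had 11 of 17 members lower and 1 higher (13 and 1 adjusted over the list alone; median -3.25, camera adjusted p = 0.000684; adjusted p = 0.304 with an estimated correlation). The rhodopsin gene ninaE stood at 553 ± 563 CPM in mock negative and 51.6 ± 13.6 CPM in mock positive libraries, and its log2 fold change moved from -3.42 to -2.41 without mock negative library 1. The transmitter receptor list moved with these, with 6 of 11 members lower and 1 higher (8 and 1 adjusted over the list alone; median -1.35, camera adjusted p = 0.0136; adjusted p = 0.472 with an estimated correlation). Oamb, an octopamine receptor gene, changed by -1.38 ± 0.27 and the dopamine receptor gene Dop1R1 by 1.74 ± 0.24. Lists for hemocytes (0 of 11 called, median 1.26), fat body (1 of 12 higher, median -0.90), muscle (0 of 11, median -0.88) and sex composition (1 of 7 lower, 0 adjusted over the list alone, median -0.88) were not called (camera adjusted p = 0.369, 0.378, 0.369 and 0.359).

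Among the metabolic lists, camera called both lipid lists higher and the respiratory chain lower, in a fraction whose neuronal marker score was lower (7.33 against 8.55). The respiratory chain call was weak, since a camera p as small came from 15 of the 35 splits of the mock libraries. Fatty acid oxidation had 15 of 19 members higher and none lower (16 adjusted over the list alone; median 1.54, camera adjusted p = 5.69e-08; adjusted p = 0.171 with an estimated correlation). The beta-oxidation enzyme genes Mtpalpha and yip2 rose by 1.76 ± 0.26 and 2.39 ± 0.38. Lipid synthesis and storage had 9 of 21 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.96, camera adjusted p = 0.000296; adjusted p = 0.17 with an estimated correlation), with the desaturase gene Desat1 up by 1.35 ± 0.17 and the lipoprotein receptor gene LpR2 by 1.51 ± 0.20. The respiratory chain list, with 3 of 40 lower among all genes and 0 adjusted over the list alone, had a median of -0.30 (camera adjusted p = 0.000773; adjusted p = 0.746 with an estimated correlation). Glycolysis had 2 of 13 higher (1 adjusted over the list alone; median 0.34, camera adjusted p = 0.135, and 0.0474 without mock negative library 2), among them the hexokinase gene Hex-A (1.70 ± 0.27). Sugar and monocarboxylate transport had 5 of 11 higher and 3 lower (5 and 4 adjusted over the list alone; median 0.67, camera adjusted p = 0.369), with the transporter gene kar at 2.25 ± 0.29 and Mct1 at -2.51 ± 0.38. The TCA cycle had 2 of 17 higher and 2 lower, adjusted over the list alone too (median -0.16, camera adjusted p = 0.697), Idh at 1.66 ± 0.19 and the citrate synthase gene kdn at -1.76 ± 0.31. No mitochondrially encoded gene of 13 was called (median -0.42, camera adjusted p = 0.185, and 0.0109 without mock negative library 1).

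Glutamate and GABA handling had 2 of 12 higher and 3 lower (4 and 5 adjusted over the list alone; median -0.21 with the test pointing up, camera adjusted p = 0.989), with the GABA transaminase gene Gabat at 1.53 ± 0.23. Ribosomal protein genes had 1 of 53 higher and 0 adjusted over the list alone (median 0.22, camera adjusted p = 0.248, but 0.0228 without mock positive library 2 and 0.000776 without mock negative library 3). Clock genes had 5 of 12 higher and 1 lower, adjusted over the list alone too (median 0.42, camera adjusted p = 0.137), and the clock transcription factor gene vri rose by 2.60 ± 0.40. Engulfment genes had 4 of 13 higher and 1 lower, adjusted over the list alone too (median 0.65, camera adjusted p = 0.0886), among them the scavenger receptor gene crq (1.06 ± 0.14).

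Of the immune and stress lists, camera called IMD and Toll signalling, JNK signalling, oxidative stress and starvation genes higher in the GFP-positive fraction, each call lost with an estimated correlation. It did not call heat shock, antimicrobial peptide or Turandot genes. The hemocyte marker score was 1.64 ± 1.33 in the GFP-positive and -0.23 ± 1.8 in the GFP-negative fraction (mean ± SD, n = 4), and that list was not called. Mock positive library 1 stood at 3.62 and the others of its group at 0.7 to 1.13. IMD and Toll signalling had 14 of 27 members higher and 1 lower (16 and 1 adjusted over the list alone; median 0.97, camera adjusted p = 5.98e-05; adjusted p = 0.286 with an estimated correlation). The Toll ligand gene spz rose by 2.71 ± 0.28, the NF-kappaB gene dl by 3.71 ± 0.57 and the inhibitor gene cact by 0.97 ± 0.16. JNK signalling had 6 of 12 higher and 1 lower (6 and 2 adjusted over the list alone; median 0.98, camera adjusted p = 0.0339; adjusted p = 0.304 with an estimated correlation), at adjusted p = 0.0557 without mock negative library 1 and 0.0504 without library 4 of that group. Its targets Mmp1 and puc rose by 2.42 ± 0.32 and 1.27 ± 0.24. Oxidative stress and detoxification had 12 of 25 higher, adjusted over the list alone too (median 1.06, camera adjusted p = 4.35e-05; adjusted p = 0.304 with an estimated correlation), such as the catalase gene Cat (1.39 ± 0.22) and GstD9 (2.80 ± 0.33), which lies in a cluster of near-identical copies. Starvation and FOXO genes had 7 of 16 higher and 2 lower, adjusted over the list alone too (median 0.70, camera adjusted p = 0.00277; adjusted p = 0.286 with an estimated correlation), with the insulin-like peptide gene Ilp6 at 3.68 ± 0.37 and the translation repressor gene Thor at 2.33 ± 0.34. Heat shock genes had 3 of 17 higher, adjusted over the list alone too (median -0.15 with the test pointing up, camera adjusted p = 0.948), among them the constitutive chaperone gene Hsc70-3 (0.90 ± 0.14). Antimicrobial peptide genes had 3 of 16 higher among all genes and 0 adjusted over the list alone, all at under 2 CPM (median -0.19, mean 1.02, camera adjusted p = 0.807).

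The second comparison puts the same question to Ecc15-infected flies. The fractions differed there as in mock flies in the leading genes. Nt5a stood at 715 ± 149 CPM in positive and 89.9 ± 14.8 CPM in negative libraries (n = 4 each), a 7.95-fold difference. List was 14.9-fold, SPARC 12.5-fold and Pcyt2 14.5-fold higher. Jheh1, a juvenile hormone epoxide hydrolase gene, was 9.45-fold higher (265 ± 33 against 28 ± 8.32 CPM) and the cytochrome gene Cyp28d1 8.17-fold higher. Ndae1 was 5.31-fold, cpo 4.96-fold, Ptp36E 3.87-fold and the calcium release channel gene RyR 3.89-fold lower in the GFP-positive fraction. In all, 1822 genes were higher and 1737 lower (edgeR, adjusted p under 0.05), with 1282 and 1222 past a 2-fold difference.

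The 10 genes higher by smallest p, with log2 fold changes ± SE, were Nt5a (2.99 ± 0.19, adjusted p = 3.45e-07), List (3.90 ± 0.27), SPARC (3.64 ± 0.27), Gel (2.79 ± 0.21), ClC-a (3.40 ± 0.26), Jheh1 (3.24 ± 0.25), Pcyt2 (3.85 ± 0.30), Oatp58Dc (2.95 ± 0.24), Cyp28d1 (3.03 ± 0.26) and Timp (3.76 ± 0.32). The 10 lower were Ptp36E (-1.95 ± 0.21, adjusted p = 1.11e-05), Ndae1 (-2.41 ± 0.30), SmydA-8 (-4.76 ± 0.63), RyR (-1.96 ± 0.26), cpo (-2.31 ± 0.31), Ca-alpha1T (-2.47 ± 0.33), Dora (-1.06 ± 0.14), PrBP (-1.15 ± 0.16), Gfrl (-2.11 ± 0.29) and Pgant9 (-2.10 ± 0.29). Socs36E rose by 1.71 ± 0.29 (adjusted p = 0.000501). The gene repo did not pass the test (1.23 ± 0.47, adjusted p = 0.0591, but 1.75 and 0.00951 without Ecc15 negative library 4), nor did Stat92E (-0.04 ± 0.15, adjusted p = 0.879). The receptor gene dome rose by 0.88 ± 0.29 (adjusted p = 0.0327), at 0.0738 to 0.0965 without Ecc15 positive library 1 or 4 or Ecc15 negative library 2 or 3.

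Gene lists gave the following picture in infected flies. Fatty acid oxidation had 15 of 19 members higher (17 adjusted over the list alone; median 1.92, camera adjusted p = 4.36e-10; adjusted p = 0.153 with an estimated correlation), with Mtpalpha at 2.17 ± 0.26 and yip2 at 3.05 ± 0.39. Oxidative stress and detoxification had 16 of 25 higher (17 adjusted over the list alone; median 1.63, camera adjusted p = 1.67e-07; adjusted p = 0.173 with an estimated correlation), and Cat rose by 1.71 ± 0.22. Glycolysis, with 4 of 13 higher and 9 adjusted over the list alone (median 0.57, camera adjusted p = 0.0178; adjusted p = 0.635 with an estimated correlation), was called, though not without Ecc15 negative library 1 (adjusted p = 0.0673). Hex-A rose there by 1.44 ± 0.27. Lipid synthesis had 12 of 21 higher and 2 lower (13 and 2 adjusted over the list alone; median 0.99, camera adjusted p = 0.000837; adjusted p = 0.153 with an estimated correlation), and the lipocalin gene GLaz rose by 2.78 ± 0.34. The respiratory chain (1 of 40 lower, 0 adjusted over the list alone, median -0.10), the TCA cycle (2 of 17 higher and 2 lower, adjusted over the list alone too, median -0.09, mean 0.06) and sugar transport (5 of 11 higher and 4 lower, adjusted over the list alone too, median 0.50) were not called (camera adjusted p = 0.201, 0.987 and 0.436). Mitochondrially encoded genes (0 of 13, median -0.34) reached camera adjusted p = 0.4, and 0.0189 without Ecc15 negative library 1. Ribosomal protein genes had 4 of 53 higher and 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.00159; adjusted p = 0.82 with an estimated correlation; 0.108 without Ecc15 negative library 1).

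Of the immune and stress lists in infected flies, IMD and Toll signalling had 14 of 27 higher and 1 lower (17 and 2 adjusted over the list alone; median 1.21, camera adjusted p = 3.12e-05; adjusted p = 0.173 with an estimated correlation). Its member PGRP-LB, the gene of a peptidoglycan-degrading amidase, stood at 3.84 ± 0.58. JNK signalling had 7 of 12 higher and 1 lower, adjusted over the list alone too (median 1.33, camera adjusted p = 0.0119; adjusted p = 0.212 with an estimated correlation). Starvation and FOXO genes had 7 of 16 higher and 1 lower (7 and 2 adjusted over the list alone; median 0.96, camera adjusted p = 0.00131; adjusted p = 0.173 with an estimated correlation), and Ilp6 rose by 4.20 ± 0.38. The JAK/STAT list (6 of 15 higher and 2 lower, 7 and 2 adjusted over the list alone, median 0.19), Turandot genes (0 of 4, median 0.50), antimicrobial peptide genes (1 of 16 higher, adjusted over the list alone too, median 2.07) and heat shock genes (3 of 17 higher, adjusted over the list alone too, median 0.07, or -0.01 with library-size scaling) were not called (camera adjusted p = 0.472, 0.689, 0.3 and 0.678). Engulfment genes (4 of 13 higher and 1 lower, 8 and 3 adjusted over the list alone, median 0.94) reached 0.0649, and 0.0244 without Ecc15 negative library 4. Clock genes (5 of 12 higher and 1 lower, adjusted over the list alone too, median 0.23) reached 0.259.

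Cell type markers in infected flies parted as in mock flies. Blood-brain barrier markers had 9 of 12 higher and 1 lower, adjusted over the list alone too (median 3.21, camera adjusted p = 4.54e-06; adjusted p = 0.0255 with an estimated correlation), and Tret1-1 rose 34.4-fold, or by 6.06 in log2 without Ecc15 negative library 2 against 5.10 ± 0.67 with it. All 3 ensheathing markers rose (median 1.63, camera adjusted p = 0.000837; adjusted p = 0.153 with an estimated correlation), rumpel by 3.45 ± 0.32 and drpr by 0.86 ± 0.20. Cortex markers had 2 of 3 higher and 1 lower (median 2.39, camera adjusted p = 0.035; adjusted p = 0.3 with an estimated correlation; 0.136 without Ecc15 negative library 1). Astrocyte-like markers had 4 of 5 lower, adjusted over the list alone too (median -1.64, camera adjusted p = 0.035; adjusted p = 0.549 with an estimated correlation; 0.168 without Ecc15 negative library 4 and 0.0609 without Ecc15 positive library 3). Neuronal markers had 15 of 16 lower (15 lower and 1 higher adjusted over the list alone; median -1.78, camera adjusted p = 1.15e-08; adjusted p = 0.3 with an estimated correlation), with ChAT at -2.12 ± 0.37. Photoreceptor markers had 7 of 17 lower and 1 higher (12 and 1 adjusted over the list alone; median -2.81, camera adjusted p = 0.0119; adjusted p = 0.487 with an estimated correlation), and ninaE moved from -3.05 to -1.72 without Ecc15 negative library 1. Transmitter receptors had 8 of 11 lower and 1 higher, adjusted over the list alone too (median -1.70, camera adjusted p = 0.00168; adjusted p = 0.384 with an estimated correlation), with the GABA receptor gene GABA-B-R2 at -1.78 ± 0.35.

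The remaining lists of the infected flies were not called. Glutamate and GABA handling had 4 of 12 higher and 5 lower (5 and 5 adjusted over the list alone; median -0.30 with the test pointing up, camera adjusted p = 0.997), with Gabat at 1.90 ± 0.23. Pan-glial markers (1 of 7 higher, adjusted over the list alone too, median 0.02, mean -0.23) had camera adjusted p = 0.513, hemocyte markers (1 of 11 lower, 0 adjusted over the list alone, median 1.40) 0.407 and fat body markers (1 of 12 higher, adjusted over the list alone too, median -0.65) 0.602. RLE factors and library-size scaling turned the pan-glial median below 0. Sex composition markers had 2 of 7 lower, adjusted over the list alone too (median -0.63, camera adjusted p = 0.371). The muscle list (1 of 11 higher, adjusted over the list alone too, median 2.42, camera adjusted p = 0.689) owed its call to Act88F, an actin gene of flight muscle, whose log2 fold change fell from 6.19 ± 1.59 to 0.62 without Ecc15 positive library 4.

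**Figure D3:**
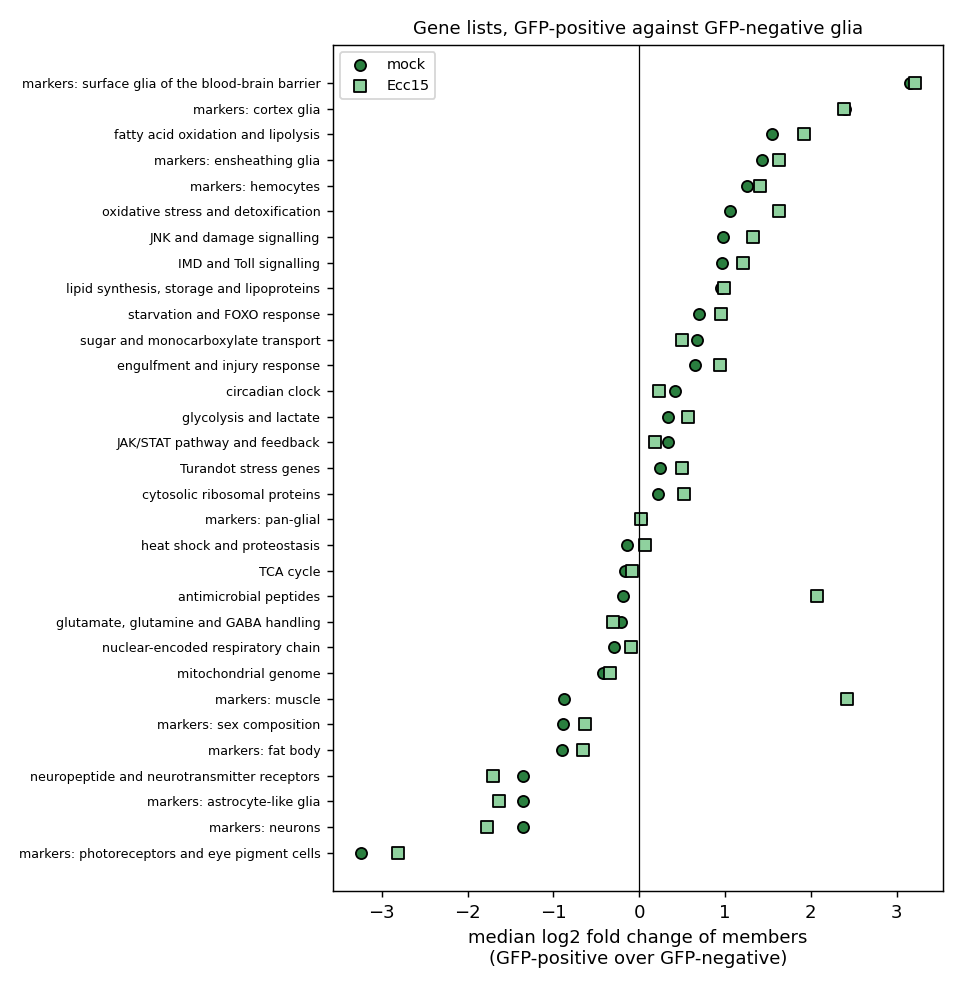
Median log2 fold change, GFP-positive over GFP-negative, of the tested members of each of the 31 gene lists in mock (circles) and Ecc15 (squares) flies. Blood-brain barrier markers are highest in both (3.15 and 3.21) and photoreceptor markers lowest (-3.25 and -2.81), and the antimicrobial peptide (-0.19 and 2.07) and muscle lists (-0.88 and 2.42) lie apart between the infection states.

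The infection states gave closely related differences between the fractions. Across 11752 genes, which are not independent replicates, the log2 fold changes of mock and infected flies had Pearson's r = 0.745 and Spearman's rho = 0.774, from separate libraries. The residuals link negative libraries of equal number, so the states are not fully independent, and r was 0.629 without mock negative library 1. Of the genes called, 1371 were higher in both states (244 expected of independent lists), 1149 lower in both (196 expected) and 0 were called in opposite directions. Averaged over the states, 2586 genes were higher and 2408 lower in GFP-positive glia (edgeR, adjusted p under 0.05). The leading genes were again Nt5a (2.88 ± 0.13, adjusted p = 4.38e-09) and List (3.99 ± 0.19), joined by the neurexin-family gene axo (3.56 ± 0.22) and, among the lower, the metalloprotease gene mmd (-2.81 ± 0.28). In this larger contrast repo was 2.29-fold higher (adjusted p = 0.00838; FBgn0011701, 3R 18236192 to 18239602), dome 1.83-fold higher (adjusted p = 0.00299) and Socs36E 3-fold higher in GFP-positive glia (adjusted p = 1.73e-05; FBgn0041184, 2L 18138675 to 18152417), and Stat92E did not pass (-0.06 ± 0.11, adjusted p = 0.717).

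The third comparison sets infected against mock GFP-positive glia. The sort used the STAT reporter itself, so a cell whose reporter changed with infection would have changed fraction. Infection contrasts within a fraction, and their difference, cannot tell such a shift of cells from regulation, and this was not tested. No single gene passed the test in edgeR (smallest adjusted p = 1), and camera called the antimicrobial peptide and heat shock lists higher. With an estimated correlation the first was called (adjusted p = 0.0158) and heat shock was not (adjusted p = 0.372). AttD, an attacin antimicrobial peptide gene (FBgn0038530, 3R 17625268 to 17626086), stood at 4.98 ± 2.62 CPM in infected and 0.624 ± 0.507 CPM in mock libraries (n = 4 each, log2 3.00 ± 0.87, adjusted p = 1), with all 4 infected libraries above all 4 mock libraries. The chaperone gene Hsp83 stood at 4026 ± 1083 against 2285 ± 585 CPM (0.82 ± 0.34) and the metchnikowin gene Mtk at 4.77 ± 2.88 against 1.09 ± 1.25 CPM (2.14 ± 1.03). The genes of the cytokines upd2 and upd3 stood at 4.36 ± 1.75 against 1.45 ± 1.33 CPM and 3.67 ± 1.99 against 1.88 ± 1.17 CPM, and neither passed the test (1.59 ± 1.37 and 0.96 ± 1.09, adjusted p = 1). At an unadjusted p under 0.05 edgeR gave 83 genes, where 588 are expected by chance, and limma with quality weights gave 636. DESeq2 called 1 gene, CG8321 (0.75 ± 0.16, adjusted p = 0.0434), and limma with library quality weights 1, the branched-chain aminotransferase gene Bcat (1.46 ± 0.15, adjusted p = 0.000484; FBgn0030482, X 13396899 to 13401224). Both were chosen after their values were seen. Bcat stood at 92.4 ± 14.7 against 30.2 ± 4.19 CPM (1.61 ± 0.40 in edgeR, adjusted p = 1) and was called by edgeR too when the GFP-positive libraries were fitted alone (1.61 ± 0.16, adjusted p = 0.0208).

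No list had a member called among all genes in this comparison. The antimicrobial peptide list rose (median 0.73, camera adjusted p = 2.65e-08; adjusted p = 0.0158 with an estimated correlation; 0 of 16 adjusted over the list alone), although the self-contained fry test gave adjusted p = 0.186. Its members lay near the floor, with a mean log2 CPM of -0.82 in infected and -2.04 in mock positive libraries. The heat shock list was called higher (median 0.50, camera adjusted p = 3.59e-11; adjusted p = 0.372 with an estimated correlation), with the small heat shock protein gene Hsp27 at 0.91 ± 0.44 and the co-chaperone gene stv at 0.76 ± 0.38. Both list calls held whichever library was left out. The glycolysis (median 0.15, camera adjusted p = 0.00108) and fatty acid oxidation lists (median 0.25, 0.000254) were called, with adjusted p = 0.544 and 0.423 with an estimated correlation. They were not called without Ecc15 positive library 1 (0.0555 and 0.148) or, for glycolysis, mock positive library 2 (0.128). IMD and Toll signalling (median 0.16, camera adjusted p = 0.00289; adjusted p = 0.423 with an estimated correlation) was lost without Ecc15 positive library 1 (0.23), and its member Rel, the NF-kappaB gene of the IMD pathway, stood at 0.50 ± 0.36. The mitochondrial genome list, with mt:ND1 at -0.43 ± 0.44, was called lower (median -0.30, camera adjusted p = 0.000254; adjusted p = 0.546 with an estimated correlation), but not without mock positive library 3 (0.207).

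The muscle list rose most in this comparison (median 3.13, camera adjusted p = 2.53e-06; adjusted p = 0.422 with an estimated correlation; 5 of 11 higher adjusted over the list alone), and without Ecc15 positive library 4 its median was -0.03 and adjusted p = 0.92. Act88F reached 129 CPM in that library and at most 0.494 CPM in the mock positive libraries. The JAK/STAT (median 0.10, camera adjusted p = 0.0346; adjusted p = 0.372 with an estimated correlation), Turandot (median 0.54, 0.0346; 0.422 with an estimated correlation) and ensheathing marker lists (median 0.27, 0.0346; 0.422 with an estimated correlation) were called. Without mock positive library 3 these stood at 0.237, 0.393 and 0.196, and without Ecc15 positive library 1 at 0.101, 0.0606 and 0.827. The JAK/STAT call also ended without mock positive library 4 (0.126) and Ecc15 positive library 2 (0.0597) or 4 (0.0568), the Turandot call without mock positive library 2 (0.0594) and Ecc15 positive library 2 (0.108) or 3 (0.0832), and the ensheathing call without mock positive library 4 (0.0803) and Ecc15 positive library 4 (0.0809). Socs36E stood at 0.39 ± 0.28 and Stat92E at 0.28 ± 0.15. Ribosomal protein genes were called lower (median -0.10, camera adjusted p = 0.0282; adjusted p = 0.859 with an estimated correlation), at 0.32, 0.273, 0.827 and 0.0556 without mock positive library 1 or 3 or Ecc15 positive library 1 or 4.

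**Figure D4:**
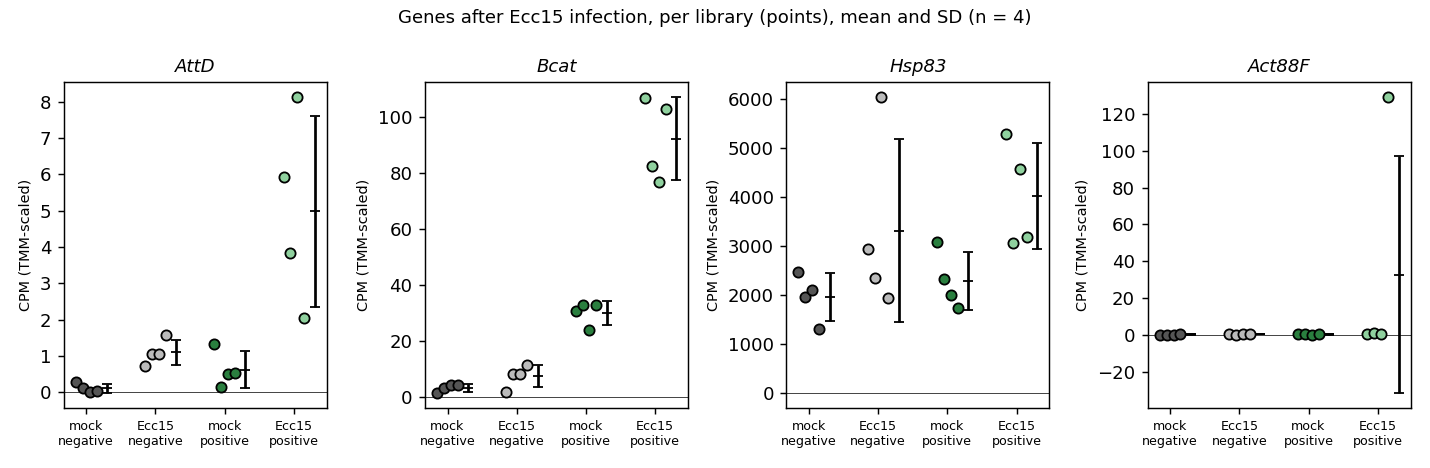
CPM (y axis, TMM-scaled) of AttD, Bcat, Hsp83 and Act88F (1 panel each) in every library (points), with mean and SD (n = 4) for the 4 groups. AttD lies higher in all infected than in all mock libraries of either fraction, Bcat in the GFP-positive fraction (92.4 against 30.2 on average), and Act88F is high (129 CPM) in Ecc15 positive library 4 alone.

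The same comparison in GFP-negative glia again gave no single gene in edgeR (smallest adjusted p = 0.584). This fit did not model the link between negative libraries of equal number. AttD stood at 1.1 ± 0.345 CPM in infected and 0.113 ± 0.129 CPM in mock libraries (n = 4 each, log2 3.21 ± 0.90, adjusted p = 0.871), again with all 4 infected libraries above all 4 mock libraries. The rhodopsin gene Rh4 stood at 8.76 ± 5.82 against 49.3 ± 31.7 CPM (-2.49 ± 0.61) and the IMD inhibitor gene pirk at 11.1 ± 16.5 against 1.12 ± 1.16 CPM (3.28 ± 1.06). At an unadjusted p under 0.05 there were 616 genes, where 588 are expected. Without mock negative library 1 there were 1554, and without both negative libraries numbered 1 there were 1210. A fit of the negative libraries alone gave 144. DESeq2 called 4 genes higher and 7 lower and limma 0. Chosen after their values were seen, these were GluProRS (0.79 ± 0.16, adjusted p = 0.00402), AttD (3.22 ± 0.78, adjusted p = 0.0412), CG43935 and TpnC47D among the higher, and dgo (-4.49 ± 0.76, adjusted p = 3.73e-05), Jheh1 (-1.27 ± 0.25, adjusted p = 0.000805), CG8343, moon, LManI, Mesh1 and Rh4 among the lower. Leaving out mock negative library 1 gave 3 calls in edgeR, CG17855, CG5397 and dgo (-4.87 in log2).

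Camera with a preset correlation called 5 lists in infected GFP-negative glia, and none of these calls held with an estimated correlation. The respiratory chain list was called lower (median -0.20, camera adjusted p = 8.84e-06; adjusted p = 0.88 with an estimated correlation), with the complex I subunit gene ND-13B at -0.37 ± 0.17, and was called whichever library was left out. The ribosomal protein list was called lower too (median -0.39, camera adjusted p = 1.16e-11; adjusted p = 0.88 with an estimated correlation), but not without Ecc15 negative library 1 (median -0.165, adjusted p = 0.137). For each of these lists a camera value as small came from 12 of the 35 splits of the libraries into 4 and 4. The mitochondrial genome list (median -0.45, camera adjusted p = 0.0037; adjusted p = 0.88 with an estimated correlation) was lost without mock negative library 3 (0.295) or 4 (0.122) or Ecc15 negative library 1 (0.758) or 2 (0.0545). Oxidative stress and detoxification genes were called lower (median -0.40, camera adjusted p = 0.00351; adjusted p = 0.88 with an estimated correlation), with Cyp6w1 at -1.10 ± 0.37. That call was lost without mock negative library 3 (0.179) or 4 (0.0644) or Ecc15 negative library 1 (0.381). Heat shock genes were called higher (median 0.50, camera adjusted p = 0.00613; adjusted p = 0.88 with an estimated correlation), with Hsp83 at 0.76 ± 0.33, but not without mock negative library 4 (0.407) or Ecc15 negative library 3 (0.675). The antimicrobial peptide list was not called (median -0.04, mean 0.65, camera adjusted p = 0.456; 1 of 16 adjusted over the list alone; median 0.04 with library-size scaling). Nor was the JAK/STAT list (median 0.16, mean -0.16, camera adjusted p = 0.353). No list had a member called among all genes, and adjusted over the list alone the photoreceptor list had 1 member lower and the sex composition list 1 higher.

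Averaged over both fractions, infection moved no gene past the threshold in edgeR (smallest adjusted p = 0.912; 439 genes at an unadjusted p under 0.05, and 952 without mock negative library 1). AttD had the log2 fold change 3.11 ± 0.63, Hsp83 0.79 ± 0.24, the phosphatidate phosphatase gene Lpin 0.63 ± 0.17 and the clock gene vri 0.92 ± 0.27. DESeq2 called 3 genes higher and 4 lower, and limma 0. Chosen after their values were seen, the DESeq2 calls were AttD (3.11 ± 0.54, adjusted p = 8.71e-05), Bcat (1.40 ± 0.29, adjusted p = 0.00697) and qin among the higher and CG33296, dgo, Jheh1 and moon among the lower. Bcat was also called by edgeR without Ecc15 negative library 1 (1.55 ± 0.19, adjusted p = 0.0123). Heat shock (median 0.54, camera adjusted p = 4.67e-08; adjusted p = 0.627 with an estimated correlation) and antimicrobial peptide genes were called higher as lists (median 0.34, camera adjusted p = 0.000368; adjusted p = 0.278 with an estimated correlation; 1 of 16 higher adjusted over the list alone). Ribosomal protein (median -0.24, camera adjusted p = 1.89e-10; adjusted p = 0.679 with an estimated correlation), mitochondrially encoded (median -0.38, 3.48e-05; 0.679 with an estimated correlation) and respiratory chain genes (median -0.10, 0.000272; 0.726 with an estimated correlation) were called lower. No list had a member called among all genes, and adjusted over the list alone the muscle list had 2 members higher and the lipid synthesis and clock lists 1 each. The respiratory chain call ended without mock negative library 3 (0.0674) or Ecc15 positive library 4 (0.0577). The muscle list (median 1.63, camera adjusted p = 0.00853; adjusted p = 0.679 with an estimated correlation) had a median of -0.15 without Ecc15 positive library 4 (adjusted p = 0.923), and was lost without mock positive library 2 (0.0593), mock negative library 1 (0.119) or Ecc15 negative library 4 (0.151).

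The last comparison asks whether the response to infection differed between the fractions. No gene differed in edgeR (smallest adjusted p = 1; 195 genes at an unadjusted p under 0.05, 541 without mock negative library 1, 588 expected), and DESeq2 and limma gave 0 as well. AttD, higher in infected libraries of both fractions, did not differ between them beyond its error (-0.22 ± 1.09), and Socs36E stood at 0.25 ± 0.39. The responses of the fractions correlated weakly across genes (r = 0.074, rho = 0.152), with 57.8% of genes on the same side of 0. With the stricter filter on low counts r was 0.272. The tests on the antimicrobial peptide (median 0.88, camera adjusted p = 0.125) and heat shock lists (median 0.10, 0.612) did not call a difference. The antimicrobial peptide list was called without mock positive library 1 (0.0368) or mock negative library 2 (0.0366), and the heat shock list without mock negative library 4 (0.0378) or Ecc15 negative library 3 (0.00208). Ribosomal protein (median 0.28, camera adjusted p = 7.54e-06), respiratory chain (0.19, 0.00036), oxidative stress (0.32, 0.000757) and fatty acid oxidation genes (0.41, 0.00363) were shifted toward the GFP-positive fraction (median and camera adjusted p in parentheses), and neuronal markers away from it (-0.41, 0.0131), each at adjusted p = 0.986 with an estimated correlation. The fatty acid oxidation members CRAT and Acox57D-d stood at 0.74 ± 0.37 and 0.91 ± 0.48. Ribosomal protein genes were not called without mock negative library 3 (0.742) or Ecc15 negative library 1 (0.836), nor were oxidative stress genes (0.0943 and 0.365), and the respiratory chain was lost without mock negative library 3 (0.157). Fatty acid oxidation was lost without mock negative library 4 (0.205) or either library 1 of the infected groups (0.137 positive, 0.618 negative). The neuronal call ended on leaving out any of 8 libraries (0.0607 to 0.634), namely mock positive 2, 3 and 4, mock negative 3 and 4, Ecc15 positive 1 and 4 and Ecc15 negative 1. The muscle list (2.95, 0.000757; adjusted p = 0.986 with an estimated correlation) ended without Ecc15 positive library 4 (0.997), Ecc15 negative library 1 (0.0545) or 2 (0.063).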

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

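The tests of astrocyte-like markers, of subtype shares, of exchanged labels and of the muscle list without 1 library were chosen after the result was seen. So were the measure behind the list differences between the fractions, the splits for the average and the difference that part every pair, and the ratio of the second muscle list to the median library. The splits of the libraries, the fit of the positive libraries alone, the negative libraries numbered 1 and the second muscle list had their predictions written before their values were known.

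The real division into GFP-positive and GFP-negative glia gave more called genes than any other split tried. Of the 35 splits of the mock libraries into 4 and 4, only 1, the real one, gave as many as 2896 called genes, and the highest other gave 0. In infected flies it was again 1 of the 35 splits (3559 genes, highest other 0), and over both states 1 of the 100 splits (4994 genes, highest other 112). In each case that is the smallest share these splits can give. The other splits into 4 and 4 mixed the fractions within a group, which raises the spread and makes few calls likely.

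For the genes higher in the GFP-positive fraction, 3 explanations were weighed. RNA of neurons and photoreceptors in the negative fraction could lower the share of every glial gene there, but the median of the astrocyte-like markers was -1.35 ± 0.61 in mock and -1.64 ± 0.46 in infected flies (SD of members over the root of their number), below 0 where dilution would put it above. This argues against dilution as the whole cause, though only weakly, since a camera p as small for this list came from 11 of the 35 splits in mock (0.00927, smallest other 1.4e-09) and 22 of the 35 in infected flies (0.017, 1.64e-06). The negative libraries numbered 1, rich in photoreceptor RNA, could make the difference, but 2745 genes were called in mock flies without them, against 2896 with them, which argues against this. Different shares of glial subtypes may lie behind many of the calls, with subtype medians from -1.35 (astrocyte-like) to 3.15 (surface), and regulation within a subtype was not separated from this and remains open.

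No gene was called between Ecc15 and mock flies by edgeR in any of the 4 infection contrasts, with 83, 616, 195 and 439 genes at an unadjusted p under 0.05 in the positive fraction, the negative fraction, their difference and their average. DESeq2 called 1, 11, 0 and 7 genes and limma 1, 0, 0 and 0, and edgeR called 3 in the negative fraction without mock negative library 1 and 1 in the average without Ecc15 negative library 1. The counts at that p moved too. Without mock negative library 1 they were 1554, 541 and 952 in the negative fraction, the difference and the average, without both negative libraries numbered 1 the negative fraction had 1210, and limma gave 636 in the positive fraction. Fitted alone, the positive libraries gave 206 and the negative libraries 144. As many genes at that p came from 26 of the 35 splits of the positive libraries (highest other 666), 20 of the 35 splits of the negative libraries (3080), 99 of the 100 splits for the difference (1748) and 53 of the 100 for the average (2093). The residuals link negative libraries of equal number, which these 100 splits ignore. Of 100 splits that part every such pair, 93 gave as many genes for the difference (highest other 845) and 11 for the average (582). Among the 8 splits of the positive libraries that part every pair of equal numbers, the highest other count was 117, against 83 for the real one. Among the 8 such splits of the negative libraries, the real count of 616 was the highest (next 486). A split of the negative libraries across the groups called 399 genes, so they carry structure that infection state does not follow.

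For this absence of calls, a pair of technical explanations was weighed. The spread of the negative libraries could hide changes in the positive fraction. A fit of the 8 positive libraries alone called 1 gene, Bcat, under the bound written beforehand for no hidden changes. In this fit the standard error of Bcat fell from 0.40 to 0.16, and genes at an unadjusted p under 0.05 rose from 83 to 206. A fit of the negative libraries alone moved their count the other way, from 616 to 144. The fit of the positive libraries also tested fewer genes, 10820 against 11752. Whether the spread of the negative libraries hid the Bcat call was therefore not tested by itself. The 206 genes of this fit were also fewer than chance gives among 10820. Its few calls thus cannot decide whether changes were hidden. Exchanged labels of mock and Ecc15 libraries could hide changes too. Any exchange within the positive fraction is another of its 35 splits, and each of the others called 0 genes, as predicted if no labels were exchanged. The labels as given called 0 genes as well, so these counts cannot tell the splits apart. At an unadjusted p under 0.05 the highest other split had 666 genes against 83. It put the mock and Ecc15 positive libraries numbered 1 on the same side, and their residuals correlated at 0.24. Among the other splits of the positive libraries that part every pair of equal numbers, the highest count was 117. The 666 genes therefore cannot tell an exchange from a link between these libraries. The lowest Ecc15 library also lay below the highest mock library in antimicrobial peptide score (by -0.38). In the negative fraction another split called 399 genes and this score overlapped as well (by -0.27), so what an exchange needs is there. That split put the mock and Ecc15 libraries numbered 1 on the same side, and their residuals correlated at 0.53. Among the other splits that part every pair of equal numbers, the most genes called was 1. The 399 calls therefore cannot tell an exchange from the link between these libraries. Such an overlap also arises from a weak response. AttD parted all 4 infected from all 4 mock libraries under the labels as given, but it was picked after its values were seen and cannot decide this. The question stays open in both fractions. In simulated data 62.6% of genes changed 4-fold in the positive fraction were called and 14.2% of those changed 2-fold, so small changes may have been missed. These data gave both fractions the same mean and dispersion per gene, so the shares need not hold for the real positive fraction.

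Muscle transcripts in the infected GFP-positive glia came from Ecc15 positive library 4, where Act88F reached 129 CPM. A rise shared by the infected libraries was tested by leaving this library out, which left a median of -0.03 and argues against it. Muscle RNA in this library could be the source, and a second list of 8 muscle genes had a median log2 ratio of -0.04 ± 0.36 to the highest of the 15 other libraries, under the bound of 0.5 written beforehand. That bound was too strict, since the highest of 15 libraries can hold muscle transcripts of its own, and the members went both ways. Of the 8, 4 were above every other library, among them fln (42.9 against at most 17.8 CPM) and Strn-Mlck (39.5 against 16.9), and 7 were above the median library (median log2 ratio 1.91). Mf, TpnC41C and Mlp84B stayed below the highest other library (-0.99, -1.35 and -1.12). The values do not decide it, and the source remains open.

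Lists called by camera with a preset correlation were common in other splits too, so their number says little. As many as the 11 lists of the positive fraction came from 12 of the 35 splits (highest other 18), as many as the 5 of the negative fraction from 25 of the 35 (14), or 4 of the 8 that part every pair of equal numbers, and as many as the 6 of the difference from 72 of the 100 (20). Of the 31 lists in 7 contrasts, antimicrobial peptides and heat shock were picked for a closer test because they led the ranking in the positive fraction. Antimicrobial peptides (camera 1.71e-09, most extreme other split 2.84e-09) and heat shock genes (1.16e-12, other 6.46e-12) each were most extreme in the real division. That is 1 of the 35 splits, the smallest share these splits can give, and no correction for the picking was made. The JAK/STAT (0.0123, other 0.0162), IMD and Toll (0.000653, other 0.000728) and fatty acid oxidation lists (4.01e-05, other 4.21e-05) were also most extreme in the real division of the positive libraries. Averaged over the fractions, 4 of the 100 splits were as extreme for antimicrobial peptides (5.93e-05, most extreme other 2.82e-05) and 11 of the 100 for heat shock genes (3.01e-09, other 4.25e-18), so chance is not excluded for heat shock there. Of the 100 splits that part every linked pair, 3 were as extreme for antimicrobial peptides (other 1.7e-05), 6 for heat shock genes (2.63e-10), and 59 gave as many lists as the 6 of the difference (14). The fall of ribosomal protein genes in the negative fraction (3.73e-13) was matched by 12 of the 35 splits (most extreme other 6.37e-33). Among the 8 splits that part every pair of equal numbers, which the residuals of these libraries link, it was matched by 2 with the real one (other 4.27e-14). The fall of the respiratory chain list there (5.7e-07) was likewise matched by 12 of the 35 splits (other 1.19e-18), counted without regard to these pairs. Lists called between the fractions were matched as well. In mock flies the splits as extreme, of 35 with the real one, numbered 15 for the respiratory chain and, for the others, astrocyte-like markers 11, transmitter receptors 10, photoreceptors 9, oxidative stress 5, neurons 4 and JNK 4. In infected flies the numbers were ribosomal proteins 28, photoreceptors 22, astrocyte-like markers 22, glycolysis 14, transmitter receptors 8, lipid synthesis 4, JNK 4, neurons 3, oxidative stress 2 and ensheathing markers 2. The other called lists, 7 in mock and 5 in infected flies, were most extreme in the real division.

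The medians of 6 lists differed between the fractions in their response to infection. These were oxidative stress (0.32), respiratory chain (0.19), fatty acid oxidation (0.41), neuronal markers (-0.41), muscle (2.95) and ribosomal proteins (0.28), positive minus negative. None of these calls held with an estimated correlation (adjusted p = 0.986).

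Single libraries stood apart from the other 3 of their group in 9 of 160 groups of values tested by Dixon's ratio, where chance alone gives about 8, or 1 in 20. Mock positive library 3 had 11636 detected genes against 13145 to 13307, and a sugar and monocarboxylate transport score of 3.73 against 4.8 to 4.97 (mean log2 CPM of members, as for the scores that follow). Mock positive library 1 had a neuronal score of 6.51 against 7.56 to 7.65 and a hemocyte score of 3.62 against 0.7 to 1.13. In mock negative library 1 the glycolysis score was 8.3 against 9.04 to 9.18 and the cortex glia score 6.98 against 8.14 to 8.18. Mock negative library 2 had a sex composition score of 4.62 against 6.45 to 6.78. The astrocyte-like score of Ecc15 positive library 4 was 8.59 against 8.2 to 8.25, and the ribosomal protein score of Ecc15 negative library 1 was 6.29 against 7.49 to 7.57.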

How the results depend on the processing

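Leaving out the negative libraries numbered 1, or those numbered 3, and repeating the list tests without each library were chosen after the result was seen, and the other settings before. No gene was called in opposite directions by any setting in the contrasts between the fractions. Counts of genes higher in GFP-positive glia of mock flies ranged from 1155 to 1472 on leaving out 1 library and of genes lower from 839, without mock positive library 1, to 1416. In infected flies the ranges were 1448 to 1981 and 1273 to 1823, and averaged 2188 to 2701 and 2178 to 2659. The replicate number as a block gave 1690 higher and 1183 lower in mock flies, and a block within infection state 1432 and 791, a fall whose cause was not tested. The stricter filter, which tests fewer genes of low count, raised the correlation of the mock and infected log2 fold changes from 0.745 to 0.951 and that of the infection responses from 0.074 to 0.272, and leaving out 1 library gave 0.629 to 0.748 and 0.037 to 0.082. Scaling by library sizes moved the median log2 fold change of all genes to -0.09 in mock and -0.11 in infected flies and turned the signs of pan-glial and, in infected flies, heat shock medians, which were near 0, but of no list that camera called.

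For infection, calls changed with the tool and with libraries left out. Genes higher in the positive fraction numbered 0 with all libraries and 1 by DESeq2, 1 by limma with quality weights and 1 by edgeR on the groups compared alone, and leaving out 1 library gave 0. In the negative fraction DESeq2 called 4 higher and 7 lower, edgeR without the negative libraries numbered 1 called 4 and 2, and leaving out 1 library gave 0 to 2 higher and 0 to 1 lower, the calls coming without mock negative library 1. Averaged, DESeq2 called 3 higher and 4 lower, edgeR without the negative libraries numbered 1 called 1 higher (Bcat), and leaving out 1 library gave 0 to 1 higher, the call coming without Ecc15 negative library 1. The replicate block changed no gene call of infection (117 genes at an unadjusted p under 0.05 in the positive and 676 in the negative fraction). The cause of these differences was not tested, and the library quality weights ranged from 0.34 to 5.16.

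Several lists of the infection comparisons depended on single libraries, which ended calls and also gave new ones. In the positive fraction the adjusted p of the respiratory chain list ranged from 0.0197 without Ecc15 positive library 2 (median -0.073) to 0.973. Without Ecc15 positive library 4 it was 0.0261 in the other direction (median 0.073). Lists not called with all positive libraries reached smaller values still. Without mock positive library 1 these were neuronal (9.54e-05), receptor (0.00444), JNK (0.00558) and hemocyte lists (0.00886), and fat body markers stood at 3.79e-05 without Ecc15 positive library 1. For the difference between the fractions, glycolysis was gained in 4 of the 16 leave-outs (lowest 0.000237, without Ecc15 negative library 4) and transmitter receptors in 5 (0.00206, without mock positive library 1). The muscle median ranged from -0.030 without Ecc15 positive library 4 to 3.521, and averaged over the fractions from -0.153, again without that library, to 2.104. The ribosomal protein list ranged in adjusted p from 2.13e-09 without mock positive library 2 to 0.827 without Ecc15 positive library 1, and in median from -0.236 to 0.045, which was its value without mock positive library 3 (adjusted p = 0.273). The antimicrobial peptide list kept its call in the positive fraction with each library left out (adjusted p = 6.55e-08 to 0.00257, the highest without mock positive library 2) and with the replicate number as a block (7.01e-08), and its sign with library-size and RLE scaling. The call was lost with fry (adjusted p = 0.186), and the list was not tested with the stricter filter on low counts. Why these lists moved was not tested.

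Depth was not varied. In counts simulated at the depth and spread of these libraries, 92.9% of genes over 50 CPM with a 4-fold change were called between infected and mock GFP-positive glia and 96.4% in the negative fraction, against 62.6% and 59.9% of all genes so changed. With a 2-fold change 25% and 27.5% of genes over 50 CPM were called, and 14.2% and 11.2% of all.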

Other observations

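The tests on gene families and the single genes given here were chosen after the result was seen.

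Gene families named by a shared symbol stem were compared between the fractions, 77 of them with at least 8 tested members. Cell-surface proteins of neuronal wiring were lower in GFP-positive glia. Of 21 dpr genes, 20 were lower in mock and in infected flies (median log2 -1.46 and -1.85, camera adjusted p = 3.28e-10 and 3.86e-12), and the genes of their partners, the DIP family, were lower in 5 and 11 of 13 (median -1.24 and -1.68, camera adjusted p = 0.00125 and 0.000185). Of 13 beat genes, 8 and 11 were lower and 2 higher (median -1.22 and -1.75, camera adjusted p = 0.022 and 0.00175). With an estimated correlation none of these calls held (adjusted p = 0.997 in mock and 0.987 in infected flies). The neuronal marker score was lower in the same libraries (7.33 against 8.55 in mock and 7.27 against 8.83 in infected flies).

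Families of detoxifying enzymes were higher in GFP-positive glia. Of 75 cytochrome P450 (Cyp) genes, 24 were higher and 1 lower in mock flies and 28 and 1 in infected flies (median 0.57 and 0.58, camera adjusted p = 0.000125 and 6.28e-05; adjusted p = 0.837 and 0.581 with an estimated correlation). Of 24 UDP-glycosyltransferase (Ugt) genes, 9 and 11 were higher (median 1.74 and 1.05, camera adjusted p = 0.000523 and 0.000185; adjusted p = 0.786 and 0.409 with an estimated correlation). Of 34 glutathione transferase (Gst) genes, many of them in clusters that share reads, 12 and 15 were higher and 3 and 4 lower (median 0.95 and 1.1, camera adjusted p = 0.0295 and 0.00187; adjusted p = 0.997 and 0.792 with an estimated correlation). Apart from these enzymes, of 19 genes of serpin protease inhibitors (Spn), 7 were higher and 1 lower in both states (median 0.6 and 0.86, camera adjusted p = 0.0244 and 0.0127; adjusted p = 0.793 and 0.409 with an estimated correlation). Other scalings were not rerun on families, but the shift of all genes under library-size scaling (median -0.09 in mock and -0.11 in infected flies) was smaller than any median given here.

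Single genes between infected and mock flies were looked at per library, with 4 libraries per group. Apart from Hsp83, whose libraries overlapped, they were picked because their libraries were apart or another tool called them. No test of these genes is therefore given here. AttD in both fractions, and Bcat and CG8321 in the positive fraction, were higher in all 4 infected than in all 4 mock libraries. Bcat ranged from 76.9 to 107 CPM in infected and from 24.1 to 33.1 CPM in mock positive libraries, and overlapped in the negative fraction (7.64 ± 4.03 against 3.4 ± 1.35 CPM, mean ± SD). In the negative fraction GluProRS (29.6 ± 2.62 against 17.2 ± 2.9 CPM), Jheh1 (28 ± 8.32 against 68 ± 21.8) and Rh4 (8.76 ± 5.82 against 49.3 ± 31.7) were separated between the groups in all 4 against all 4 libraries. Hsp83 in the positive fraction ranged from 3056 to 5287 CPM in infected and from 1726 to 3082 CPM in mock libraries.

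Bcat was the 1 gene called by edgeR in the fit of the positive libraries alone, and it was not called with all libraries. The difference of its response between the fractions was not called by edgeR either (log2 0.44 ± 0.55, adjusted p = 1).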
